A study of Homo sapiens with 6 samples.

How the data were processed

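Gene expression was measured in cultured mesenchymal stromal cells (MSCs), the adherent cells of bone marrow aspirates. There were 6 samples on 6 short-oligonucleotide arrays, 2 in each of 3 groups: normal MSCs at early passage (passage 2 to 3), normal MSCs at later passage (passage 7 to 9), and MSCs of patients with large granular lymphocyte leukaemia (LGLL) at passage 7 to 9. The labels describe the passage state of the LGLL cultures as later, with senescence. Per the labels' protocols, cultures were grown with 10% serum and under 2% oxygen, and 100 ng of total RNA was amplified and labelled with biotin. The 2 samples of a group are labelled biological replicates, with no statement of donors, so p-values measure the spread between these samples. Whether the early- and later-passage normal cultures came from the same donors is not given in the sources used here.

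The deposited values were one linear signal intensity per probe set and array. Per the submitters' processing notes, GCOS 1.4 and MAS5 were used. On every array the mean after trimming 2% at each end was 500.1, the global scaling of MAS5, and no log transformation or centring had been applied. Detection calls were not used here, so whether a low signal lies above background is unknown. No pair of arrays held identical values (0 pairs). Of 54675 probe sets, 41097 had 1 gene symbol in the platform annotation, 1801 had several and 11777 had none; only those with 1 symbol were named. Entrez identifiers of 41043 probe sets matched the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols, and 1 symbol of the gene lists was replaced by its newer name. The 62 control probe sets and 65 probe sets of sex-linked genes were left out. Every column of the table was mapped to a sample.

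From the deposited intensities, log2(signal + 16) was computed with no further normalization. Log2 changes on this scale understate the change of genes with low signal. Each gene was represented by the probe set with the highest mean over the 6 arrays. Genes with a mean at or above the median of all probe sets, 6.37 on the log2 scale, were tested, which kept 12613 of 19740 genes. A linear model with 1 mean per group was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, with moderated variances and an intensity trend. There were 3 residual degrees of freedom and 3.14 prior degrees of freedom. P-values were two-sided, adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 are called changed. Exact permutation of 2 against 2 arrays cannot give a p under 0.333, so every test rests on limma's pooled spread. The number of arrays limits the precision.

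There were 4 comparisons: LGLL against later-passage normal MSCs, LGLL against early-passage normal MSCs, later against early passage in normal MSCs, and LGLL against the mean of both normal groups. Further, 35 gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over 140 pairs of list and comparison. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera has only the 3 residual degrees of freedom and so little power. A list that fails it is therefore not shown to be unchanged, nor is the preset correlation shown to hold. For lists, called members were counted over all genes tested and again with p-values adjusted over the list alone. Overlaps between comparisons that share arrays were set beside 100 simulations of unchanged groups and beside the overlap of independent lists.

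Tests, lists and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, up to 10 called genes with the largest increase and 10 with the largest decrease whose groups do not overlap. A direction with fewer than 5 called genes would be filled to 5 with the smallest unadjusted p. Up to 4 members with the smallest p are added for each list, and FGF2, MKI67, TOP2A, CDKN1A, CDKN2A, LMNB1, COL1A1, COL3A1, IL6 and CXCL12 are always included. Genes with common germline deletions or alleles that probes can miss are not named. The text draws on 187 gene values for 126 genes chosen by this rule. Outside it, TNFRSF21, the levels of PTPRC, HLA-DRA and C1QA on single arrays and the value of VIM were chosen after they were seen. For 95 of these values the gene had further probe sets above the intensity filter, and for 0 of them did a further probe set change by more than 0.5 in the opposite direction.

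The procedure was tested on 20 simulated data sets of 12613 genes with 200 genes changed in LGLL. For LGLL against later-passage normal MSCs it recovered 18.9% of genes changed by 1 on the log2 scale, 80.4% of those changed by 2 and 98.9% of those changed by 4, with a mean of 10.4 false calls. For LGLL against early-passage normal MSCs these values were 18.2%, 79.3%, 98.7% and 9.35. Recovery in the data may differ. Each simulated gene had the same spread in every group, while the early-passage pair correlated less than the others. The 200 changed genes are also far fewer than the 5201 called in LGLL against later passage. A list of 18 genes raised by 1 passed camera in 20 of 20 simulated sets, each with 140 pairs of list and comparison. Over all 20 sets together 24 unchanged pairs passed as well, so false passes outnumbered the sets. Camera's adjusted p-values are therefore not shown to hold false passes to their stated rate. The noise was drawn for each gene independently. These runs therefore do not test camera where the members of a list vary together. Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, other filters, the mean of all probe sets, other variance settings, other thresholds, the compared arrays alone, the replicate number as a block and each array left out. For the list medians only quantile normalization was planned, and all other alternatives were added after the data were seen. Figures were drawn with matplotlib 3.10.9.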

Results

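The samples allow 3 questions about bone marrow MSCs in LGLL, a disease of clonal cytotoxic lymphocytes. Per the submitters' description of the series, later-passage normal cultures match the LGLL cultures in time spent growing and early-passage normal cultures match them in population doublings; the counts of doublings are not given in the sources used here. The LGLL cultures can be set beside each of these groups and beside both. The later-passage normal arrays stood apart from the other 4. Over the 12613 genes tested, their Spearman correlation with the early-passage arrays was 0.754 to 0.766 and with the LGLL arrays 0.747 to 0.755, while the pair itself reached 0.972. The LGLL pair correlated at 0.965 and the early-passage pair at 0.93. Early-passage replicate 1 correlated with the LGLL arrays at 0.945 and 0.951, above its correlation with early-passage replicate 2, which reached only 0.897 and 0.898 with the LGLL arrays. Early-passage replicate 2 also carried more monocyte and macrophage transcripts than replicate 1: PTPRC, the common leukocyte antigen CD45, was at 11.03 against 6.87, HLA-DRA at 14.29 against 9.68 and C1QA at 11.13 against 6.9. All 15 tested macrophage markers were higher in replicate 2, by a median of 3.14, and 26 of 26 interferon response genes by a median of 2.9, while fibroblast and MSC markers differed by a median of 0.15. In the LGLL pair the 15 macrophage markers were all lower in replicate 2, by a median of 1.76. The mean of these markers was 8.09 on early-passage replicate 1 and 8.01 on LGLL replicate 1. It was 5.97 on LGLL replicate 2 and 5.88 and 5.79 on the later-passage arrays. Median signals per array were 60.9 to 73.8, and the 3' minus 5' differences were -0.16 to -0.09 for GAPDH and 0.06 to 0.14 for ACTB on the log2 scale.

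**Figure D1:**
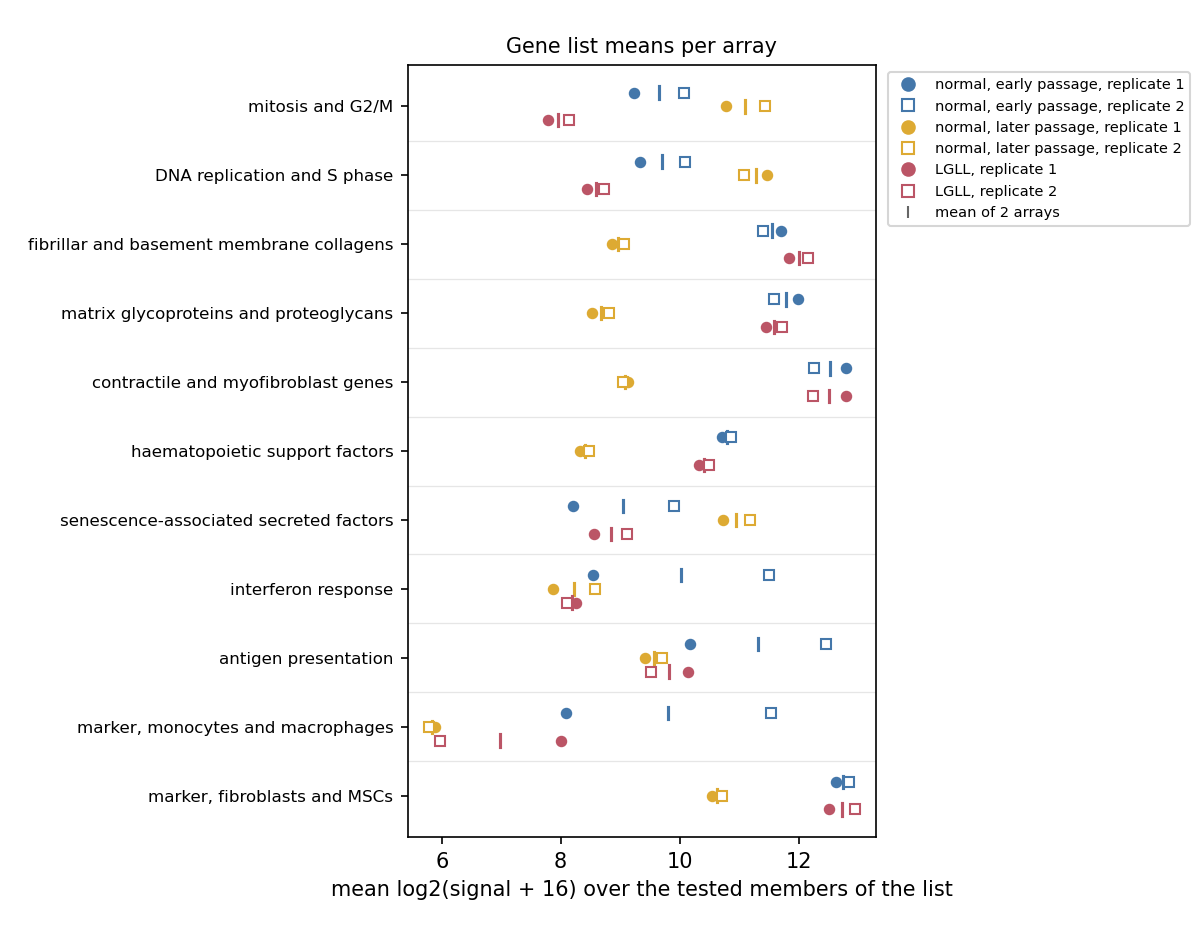
Mean log2(signal + 16) over the tested members of gene lists (vertical axis: lists) on each of the 6 arrays, with bars for the mean of the 2 arrays of a group. The later-passage normal arrays are highest for cell-cycle genes and lowest for matrix and contractile genes, and early-passage replicate 2 is highest for interferon, antigen presentation and macrophage genes.

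LGLL MSCs had higher stromal and matrix transcripts and lower cell-cycle transcripts than later-passage normal MSCs, the group described as matched for time. The lists of these genes passed the set test, but not with an estimated correlation (lowest adjusted p = 0.482). CXCL12, the chemokine that retains haematopoietic cells in the marrow, rose from 4.89 (SD 0.39) to 13.65 (SD 0.32), a log2 change of 8.77 (SE 0.26, adjusted p = 0.000107, 2 arrays per group). COL8A1 rose by 9.41 (SE 0.42, adjusted p = 0.000156) and LUM, a proteoglycan of collagen matrix, by 7.85 (SE 0.23). The granulocyte growth factor CSF3 fell by 7.99 (SE 0.65, adjusted p = 0.000654) and the complement component C3 fell by 8.65 (SE 1.06, adjusted p = 0.00215). Of 12613 genes, 5201 were called, 2526 higher and 2675 lower in LGLL, and 3759 of them changed at least 2-fold. The largest increases included MEST (9.02), IGFBP2 (8.69), DKK3 (8.34), CDH11 (8.33), RGS4 (8.26), SCUBE3 (8.08) and COX7A1 (7.89). The largest decreases included CCL20 (-7.85), GPAT2 (-7.72), SPRR3 (-7.35), IL1A (-7.34), IL13RA2 (-7.21), EPB41L3 (-7.20), CXCL3 (-7.15) and SPRR2B (-6.97).

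All 25 tested mitosis genes fell, 25 also when adjusted over the list alone, with a median of -3.26; CDK1 (-4.71), CDC20 (-3.72), TOP2A (-3.45) and MKI67 (-2.46) were among them (adjusted p = 0.524 for the list with an estimated correlation). All 25 DNA replication genes fell as well, 25 adjusted over the list alone, among them MCM2 (-4.07) and MCM7 (-2.97) (adjusted p = 0.503 for the list with an estimated correlation). LMNB1, a nuclear lamina gene lost in senescent cells, fell by 3.13, and CDKN1A rose by 1.39. CDKN2A, which encodes the inhibitor p16, changed by -0.86 and did not pass (adjusted p = 0.217); without LGLL replicate 1 its change was -1.65 and passed. Of 13 tested cell cycle inhibitors and senescence markers, 2 rose, 6 fell and 5 did not pass (3 and 6 over the list alone), with CDKN1C at -2.78. Of 19 p53 targets, 10 rose, 4 fell and 5 did not pass (10 and 4 over the list alone). ZMAT3 rose by 2.73 and XPC fell by 2.60. Neither list passed the set test (adjusted p = 0.178 and 0.111), though the p53 targets did with no filter (1.22). With fry the cell cycle inhibitors and senescence markers passed (adjusted p = 0.0243) and the p53 targets did not (adjusted p = 0.0666). The first list mixes LMNB1, which falls in senescent cells, with inhibitors that may rise. A test of 1 direction therefore cannot settle senescence. Among 21 senescence-associated secreted factors, 4 rose, 10 fell and 7 did not pass (4 and 10 over the list alone, median -2.73). The list did not pass camera (adjusted p = 0.0676) but passed fry (adjusted p = 0.0266), and IGFBP5 rose by 6.87. This list passed without early-passage replicate 1 or 2 (both -2.73), LGLL replicate 1 (-2.95) or LGLL replicate 2 (-2.51), and with no filter (-2.97), only the arrays compared or the replicate block. IL6 fell by 1.91 (SE 0.50, adjusted p = 0.0264), a call lost without later-passage replicate 1 (-2.00), later-passage replicate 2 (-1.82) or LGLL replicate 2 (-1.47).

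Of 24 collagens, 18 rose, 1 fell and 5 did not pass (18 and 1 adjusted over the list alone); COL5A2 rose by 4.42, COL4A1 by 4.19, COL3A1 by 3.45 and COL1A1 by 1.47 (adjusted p = 0.482 for the list with an estimated correlation). Of 18 contractile and myofibroblast genes, 16 rose and 2 did not pass (16 adjusted over the list alone), with LMOD1 at 7.14, ACTA2 at 4.80 and MYL9 at 2.45 (adjusted p = 0.482 with an estimated correlation). Of 18 fibroblast and MSC markers, 10 rose, 1 fell and 7 did not pass (10 and 1 adjusted over the list alone), with THY1 at 4.52, PDGFRA at 5.12 and PDGFRB at 5.76 (adjusted p = 0.482 with an estimated correlation). Of 21 haematopoietic support genes, 13 rose, 2 fell and 6 did not pass (13 and 2 adjusted over the list alone), VCAM1 by 6.78 (adjusted p = 0.482 with an estimated correlation). Collagen processing followed with 16 of 22 genes higher and 6 not passed (18 higher adjusted over the list alone), including ADAMTS2 (6.57) and PCOLCE2 (4.19) (adjusted p = 0.482 with an estimated correlation). In the TGF-beta list 12 of 19 rose, 2 fell and 5 did not pass (13 and 2 adjusted over the list alone), with LTBP2 at 5.88 and SMAD7 at 2.65 (adjusted p = 0.482 with an estimated correlation). The osteoprotegerin gene TNFRSF11B rose by 7.04. Of 15 macrophage markers 1 rose, 1 fell and 13 did not pass (1 and 0 over the list alone), and this list did not pass either (median 1.10, adjusted p = 0.341).

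In the FGF family 5 of 19 genes rose, 4 fell and 10 did not pass (6 and 4 over the list alone). The list did not pass (adjusted p = 0.585). FGF1 rose by 4.89, while the FGF target genes ETV4 and DUSP6 fell by 3.09 and 2.17. FGF2 fell by 1.20 (SE 0.36, adjusted p = 0.0389), a call lost without later-passage replicate 2 (-0.71), LGLL replicate 1 (-1.44) or LGLL replicate 2 (-0.95), with no filter or with no intensity trend. Among 17 HOX genes 3 rose, 1 fell and 13 did not pass (1 and 1 over the list alone). HOXB3 rose by 1.16, a call lost without LGLL replicate 1 (1.09), and HOXD9 fell by 1.71, a call lost with the mean of all probe sets (-0.23). With the mean of all probe sets, calls that stayed moved for COL8A1 (6.08), DKK3 (4.19), SCUBE3 (4.57), SPRR3 (-4.18), IL1A (-4.04), COL1A1 (3.03), PDGFRA (1.86), ACTA2 (2.13) and FGF2 (-1.81). Centring each array on its median moved the share of called genes that were higher from 48.6% to 38.6% (2096 higher, 3341 lower), since it shifts every log2 change by -0.16, the array medians over all probe sets being higher in LGLL. In 76.1% of genes the 2 groups did not overlap, where 33.3% would by chance.

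LGLL MSCs differed less from early-passage normal MSCs, the group described as matched for population doublings: 21 genes were called, 11 higher and 10 lower. ADGRF5, an adhesion receptor, rose from 5.22 (SD 0.03) to 10.78 (SD 0.58), a change of 5.56 (SE 0.36, adjusted p = 0.0127, 2 arrays per group). COL4A5, a basement membrane collagen, rose by 4.73 (SE 0.29, adjusted p = 0.0109) and the hedgehog inhibitor HHIP by 3.47 (SE 0.27, adjusted p = 0.0161). The early-response transcription factor FOS fell from 12.73 (SD 0.21) to 8.06 (SD 0.43), a change of -4.68 (SE 0.34, adjusted p = 0.0147), and CDKN1C, which encodes a cyclin-dependent kinase inhibitor, fell by 2.60 (SE 0.21, adjusted p = 0.0186). SYT16 (4.11), PRSS3 (3.33), PSG9 (3.32), ITGA2 (3.22), ZIC1 (3.15), CAVIN4 (2.75) and PCOLCE2 (2.48) also rose. RARRES2 fell by 4.99 (SE 0.30, adjusted p = 0.0109), as did GPAT2 (-4.72), TENM2 (-3.74), CXCL16 (-2.70), GAS1 (-2.51) and FNDC1 (-2.28, adjusted p = 0.0346). The immunoglobulin light chain transcripts IGLC1 (-5.42, SE 0.32) and IGLV1-44 (-5.38, SE 0.49), products of B-lineage cells, fell too. IGLC1 was at 10.53 (SD 0.37) in early passage and 5.11 (SD 0.24) in LGLL. Of 5 tested B and plasma cell markers 0 were called and 1 was lower over the list alone. Their list did not pass camera (median -1.19, adjusted p = 0.078), though fry passed it (adjusted p = 0.0496).

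**Figure D2:**
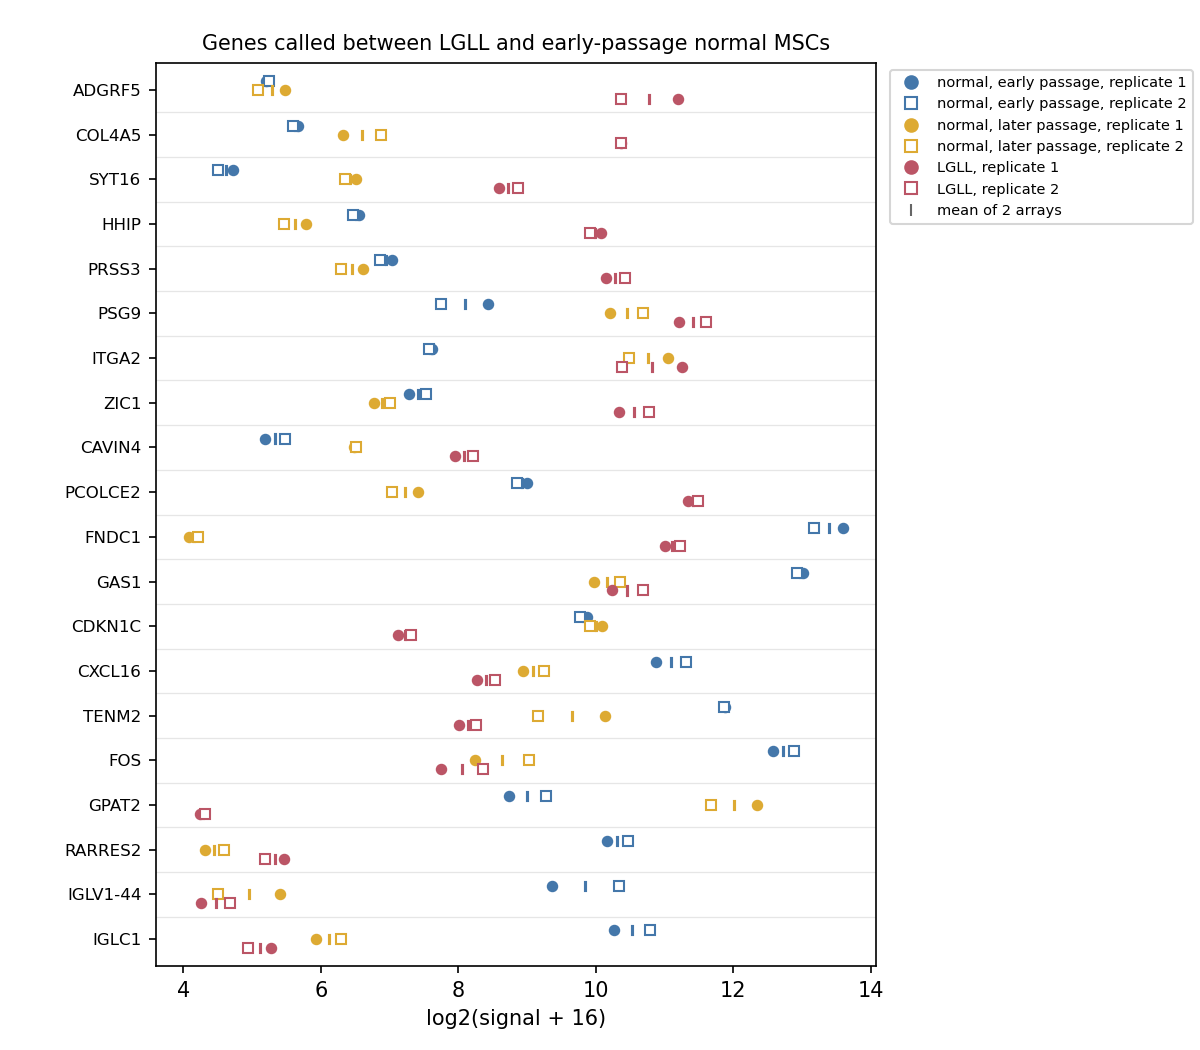
Log2(signal + 16) on each of the 6 arrays for 20 of the 21 genes called in LGLL against early-passage normal MSCs (vertical axis: genes), with bars for group means. ADGRF5 and COL4A5 are highest in LGLL, whereas IGLC1 and FOS are high in both early-passage arrays.

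These calls depended on single arrays and on the settings of the fit. Fitting only the arrays compared left 0 of the 21 called in limma (1468 genes at unadjusted p under 0.05), and the replicate block left 5 (ADGRF5, COL4A5, IGLC1, RARRES2 and FOS). With the mean of all probe sets the calls of COL4A5 (2.16), PSG9 (2.63), ITGA2 (2.56) and GAS1 (-2.36) were lost, and with a pseudocount of 64 SYT16 moved to 2.70 and GPAT2 to -3.06. The call of ITGA2 was also lost with a pseudocount of 1 (3.32) or 64 (2.94), no filter or no intensity trend, that of CAVIN4 with a pseudocount of 1 (3.34) or no filter, and that of FNDC1 with a pseudocount of 1 (-2.29). Without early-passage replicate 1 there were 350 calls (89 higher, 261 lower, including all 21), and without replicate 2 there were 11, with 6 of the 21 kept. Leaving out either later-passage array, which is not part of the comparison but adds to the estimate of spread, left 0 calls in limma (1492 and 1490 genes at unadjusted p under 0.05). Without LGLL replicate 1 or 2 limma called 0 as well (959 and 1094 at unadjusted p under 0.05). In the fit to all arrays 1497 genes had an unadjusted p under 0.05, the median absolute change was 0.255, and the groups did not overlap in 47.7% of genes, against 33.3% by chance.

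No mitosis gene passed on its own against early passage, yet the list of 25 passed with a median of -1.79 and 22 members lower when adjusted over the list alone; TTK (-2.31), TOP2A (-2.05), KIF11 (-1.97) and MKI67 (-1.65) did not pass over all genes (adjusted p = 0.482 for the list with an estimated correlation). The 25 DNA replication genes gave a median of -1.12, 0 called over all genes and 19 lower over the list alone, among them CDC45 (-2.37), RRM2 (-1.92), TK1 (-1.50) and MCM6 (-1.04) (adjusted p = 0.482 with an estimated correlation). Without early-passage replicate 1, TOP2A (-2.52), KIF11 (-2.32), TTK (-2.74), RRM2 (-2.42), CDC45 (-2.74), TK1 (-1.70) and MCM6 (-1.18) passed over all genes. Without early-passage replicate 2 the medians of the mitosis and replication lists were -1.34 and -0.73. Between the early-passage arrays, 25 of 25 mitosis genes and 24 of 25 replication genes were higher in replicate 2, by medians of 0.86 and 0.76. LMNB1 at -2.45 (adjusted p = 0.17), CDKN1A at 0.36 (adjusted p = 0.485) and CDKN2A at 1.4 (adjusted p = 0.364) did not pass; without early-passage replicate 1 LMNB1 reached -3.20 and passed. Of 13 cell cycle inhibitors and senescence markers 0 rose and 1 fell (2 and 2 over the list alone), and the list did not pass (adjusted p = 0.141). It passed without early-passage replicate 2 (0.40) and with the filter at the 75th percentile (0.50). As a list of mixed direction it cannot settle senescence here either.

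The 26 interferon response genes had a median of -1.80 with 0 called, also over the list alone; ISG20 (-1.70), IFI44L (-3.16) and OAS3 (-2.04) did not pass, and the list's adjusted p = 0.641 with an estimated correlation. The 15 macrophage markers had a median of -2.89 with 0 called, also over the list alone, with C1QA at -3.40, C1QC at -3.59 and CD163 at -2.89 (adjusted p = 0.61 with an estimated correlation). The 21 antigen presentation genes had a median of -1.39 with 0 called, also over the list alone, with HLA-DRA at -4.59 (SE 1.57) and CD74 at -3.71 (adjusted p = 0.706 with an estimated correlation). These 3 lists were higher in early-passage replicate 2, the array with the most macrophage transcripts, than in replicate 1 (median gaps 2.9, 3.14 and 2.11). So were cytokines for T and NK cells (2.23), T and NK cell markers (2.19), NF-kB targets (1.46) and senescence-associated secreted factors (1.46). Without that array the medians against early passage were -0.33 for interferon genes and -0.73 for macrophage markers, which still passed the set test, and -0.20 for antigen presentation, which did not. Without early-passage replicate 1 they were -3.33, -4.81 and -2.31, and IFI44L (-4.99), OAS3 (-3.35), C1QA (-5.52), HLA-DRA (-6.89) and CD74 (-6.00) passed over all genes. For the macrophage markers LGLL replicate 1 was level with early-passage replicate 1 (median difference -0.08) and LGLL replicate 2 lower (-1.58), and without LGLL replicate 2 the median was -1.84. The 18 immediate early genes had a median of -0.63, with FOS the only member called over all genes and 1 higher and 6 lower over the list alone; FOSB (-3.58), ZFP36 (-1.11) and JUN (-0.65) did not pass (adjusted p = 0.576 with an estimated correlation), though FOSB did without early-passage replicate 1 (-4.14).

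The 22 collagen processing genes had a median of 0.46 with PCOLCE2 the only one called, also over the list alone, and LOXL4 (1.84) and P4HA2 (0.93) not passed (adjusted p = 0.514 with an estimated correlation). Without early-passage replicate 2 this median was 0.11 and without replicate 1 0.78, and the list still passed. The 24 collagens had a median of 0.40 with COL4A5 called over all genes and 1 higher and 2 lower over the list alone; COL5A1 (0.76), COL3A1 (0.24), COL1A1 (0.21), COL8A2 (-1.48) and COL10A1 (-1.34) did not pass (adjusted p = 0.61 with an estimated correlation). The collagens no longer passed without early-passage replicate 2 (0.16), later-passage replicate 1 (0.40) or LGLL replicate 2 (0.24). Their call was also lost under quantile normalization (0.34), median centring (0.43), a pseudocount of 1 (0.40), the filter at the 75th percentile (0.23), the mean of all probe sets (0.29) and the replicate block (0.40). FGF2 at 0.71 (adjusted p = 0.488), SPRY4 at 1.42 (adjusted p = 0.0997), SPRED1 at 0.74, FGF1 at 1.30 and FGFR2 at -2.20 did not pass, and the 19 FGF family genes did not pass as a list (0 called, 2 higher over the list alone, median 0.42, adjusted p = 0.0673). The FGF list passed without early-passage replicate 1 (0.23) or LGLL replicate 1 (0.46), with the filter at the 75th percentile (0.51) and with the mean of all probe sets (0.36). CXCL12 (0.13) and IL6 (0.26) did not pass, and their direction depended on single arrays. IL6 was at -0.47 without early-passage replicate 1 and -0.19 without LGLL replicate 1, and CXCL12 at -0.09 without LGLL replicate 2. Among 13 cytokines for T and NK cells none was called (1 higher and 2 lower over the list alone), with IL7 at -2.42, which passed without early-passage replicate 1 (-2.82), and PDGFA at 0.99. The list did not pass (median -1.77, adjusted p = 0.0504). Without early-passage replicate 2 its median was 0.096. It passed without early-passage replicate 1 (-2.76) or LGLL replicate 2 (-1.72), and with quantile normalization (-1.70), median centring (-1.74), a pseudocount of 64 (-1.62), no filter (-1.44), the mean of all probe sets (-1.61) or the replicate block (-1.77).

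Later-passage normal MSCs had lower stromal, matrix and contractile transcripts and higher cell-cycle transcripts than early-passage normal MSCs. The lists of these genes passed the set test, but not with an estimated correlation (lowest adjusted p = 0.482). CXCL12 fell by 8.63, COL8A1 by 9.02 and FNDC1 by 9.24 (SE 0.23, adjusted p = 0.000112, 2 arrays per group). IL1A, an inflammatory cytokine, rose from 4.77 (SD 0.24) to 13.43 (SD 0.54), and CSF3 rose by 8.82. Of 12613 genes 4614 were called, 2294 higher and 2320 lower in later passage, 3344 of them at least 2-fold. Other large increases were IL13RA2 (8.37), SPRR3 (8.12), MMP3 (8.03), CCL20 (7.84), IL24 (7.22), ZIC2 (7.21) and SPRR2B (7.18). MMP1 rose by 8.30 (SE 1.57, adjusted p = 0.0101), a call lost without later-passage replicate 1 (8.27) or 2 (8.33). SULF1 (-8.47), MEST (-8.39), CDH11 (-8.34), IGFBP2 (-7.96), LUM (-7.95) and ID4 (-7.81) fell. LYZ, a macrophage transcript, fell by 8.19 (SE 2.03), a call lost without early-passage replicate 2 (-6.85), later-passage replicate 1 (-8.19) or later-passage replicate 2 (-8.18).

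Cell-cycle genes were higher in later than in early passage. Of 25 mitosis genes 13 rose and 12 did not pass (17 higher adjusted over the list alone), with a median of 1.54 (adjusted p = 0.706 with an estimated correlation). Of 25 DNA replication genes 18 rose and 7 did not pass (20 higher over the list alone), MCM2 by 2.78 and MCM7 by 2.19 (adjusted p = 0.609 with an estimated correlation). TOP2A rose by 1.41 (adjusted p = 0.0257), a call lost without early-passage replicate 1 (0.93), later-passage replicate 1 (1.66) or later-passage replicate 2 (1.16), and MKI67 at 0.81 (adjusted p = 0.192) did not pass. LMNB1 at 0.68 (adjusted p = 0.322) did not pass; it passed without early-passage replicate 2 (1.44) and turned to -0.07 without early-passage replicate 1. CDKN1A fell by 1.02, and CDKN2A rose by 2.26 (adjusted p = 0.0175), a call lost without early-passage replicate 1 (1.97), later-passage replicate 1 (2.38) or later-passage replicate 2 (2.14), and with the mean of all probe sets (1.20). Of 13 cell cycle inhibitors and senescence markers 6 rose, 2 fell and 5 did not pass (6 and 2 over the list alone), with HMGA2 at 4.37 and GDF15 at 2.65. The list did not pass camera (adjusted p = 0.129) but passed fry (adjusted p = 0.0266). The mixed direction of this list again leaves senescence unsettled. Among 19 p53 targets 4 rose, 9 fell and 6 did not pass (4 and 9 over the list alone), with XPC at 2.50, ZMAT3 at -2.39 and TP53INP1 at -2.46 (adjusted p = 0.141 for the list, which passed without early-passage replicate 1, at -1.04). Of 21 senescence-associated secreted factors 10 rose, 4 fell and 7 did not pass (11 and 4 over the list alone), and the list passed fry (adjusted p = 0.0243) but not camera. CXCL2 rose by 5.28 (adjusted p = 0.117 for the list, which passed without early-passage replicate 2, at 2.90, and with no filter, at 1.83). Of 17 NF-kB targets 4 rose, 1 fell and 12 did not pass (3 and 1 over the list alone), and the list did not pass (adjusted p = 0.116) except without early-passage replicate 2 (1.58). IL6 rose by 2.17 (adjusted p = 0.0195), a call lost without later-passage replicate 1 (2.26) or 2 (2.08), and by 1.44 without early-passage replicate 1.

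**Figure D3:**
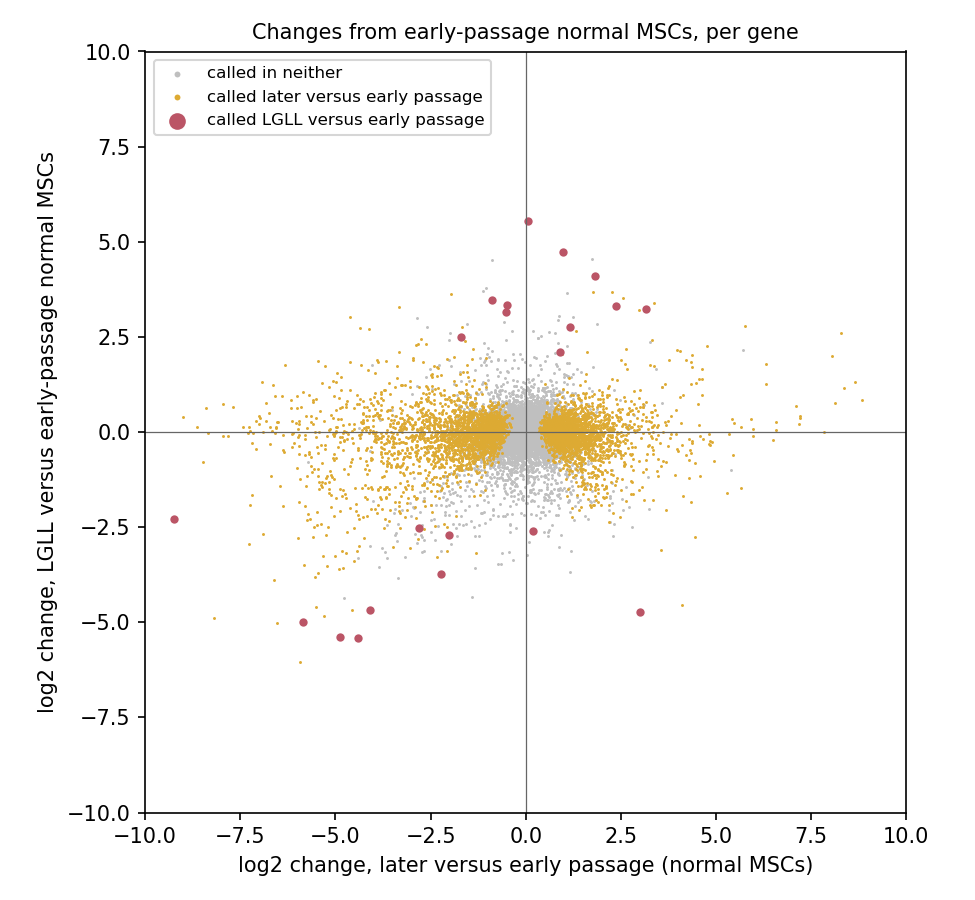
Log2 change of each tested gene from early passage in later-passage normal MSCs (horizontal axis) and in LGLL MSCs (vertical axis), 2 arrays per group. The genes called in later against early passage spread widely along the horizontal axis and lie around 0 on the vertical axis.

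Of 24 collagens 1 rose, 15 fell and 8 did not pass (3 and 16 over the list alone), COL6A3 by 6.66, COL3A1 by 3.21 and COL1A1 by 1.26 (adjusted p = 0.482 with an estimated correlation). Of 18 contractile genes 15 fell and 3 did not pass (17 lower over the list alone), with LMOD1 at -7.17 and ACTA2 at -4.81 (adjusted p = 0.482 with an estimated correlation). Fibroblast and MSC markers split into 1 higher, 10 lower and 7 not passed of 18 (1 and 10 over the list alone), with PDGFRB at -6.15 and THY1 at -4.27 (adjusted p = 0.482 with an estimated correlation). Pericyte markers split into 1 higher, 6 lower and 3 not passed of 10 (1 and 7 over the list alone), with NOTCH3 at -6.01 and MCAM at -5.37 (adjusted p = 0.524 with an estimated correlation). Of 21 haematopoietic support genes 2 rose, 15 fell and 4 did not pass (2 and 16 over the list alone), VCAM1 by 6.51 and SPP1 by 6.62 (adjusted p = 0.482 with an estimated correlation). Of 10 osteoblast genes 6 fell and 4 did not pass (7 lower over the list alone), with ALPL at -3.63; TNFRSF11B fell by 6.18 (adjusted p = 0.482 for the list with an estimated correlation). Of 19 BMP pathway genes 2 rose, 10 fell and 7 did not pass (2 and 10 over the list alone), with SMAD6 at -5.64 and ID3 at -5.06 (adjusted p = 0.653 with an estimated correlation). In the WNT list 1 of 17 rose, 7 fell and 9 did not pass (1 and 7 over the list alone), with DKK3 at -7.69 and ROR1 at -5.35 (adjusted p = 0.482 with an estimated correlation).

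FGF2 rose by 1.90 in later passage (SE 0.36, adjusted p = 0.00977) and FGF1 fell by 3.59. Of 19 FGF family genes 5 rose, 4 fell and 10 did not pass (5 and 4 over the list alone), and the list did not pass (adjusted p = 0.845). FOS fell by 4.10. Of 17 HOX genes 2 rose, 1 fell and 14 did not pass (2 and 1 over the list alone): HOXD9 rose by 1.77, a call lost with the mean of all probe sets (0.26), HOXD1 rose by 1.65, a call lost without later-passage replicate 1 (1.64), and HOXB3 fell by 1.91. With the mean of all probe sets, calls that stayed moved for COL8A1 (-5.66), ID4 (-4.85), IL1A (4.86), SPRR3 (4.83), COL1A1 (-2.81), ACTA2 (-2.66), NOTCH3 (-3.92), MCAM (-3.15), DKK3 (-3.60), TP53INP1 (-1.05), CXCL2 (2.57), GDF15 (1.13) and HMGA2 (2.13). Centring each array on its median moved the share of called genes that were higher from 49.7% to 62.2% (3173 higher, 1929 lower), since it shifts every log2 change by 0.185, the array medians over all probe sets being lower in later passage. The groups did not overlap in 71.9% of genes, against 33.3% by chance.

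Against the mean of both normal groups, LGLL MSCs had 2453 called genes, 1243 higher and 1210 lower, 1564 of them at least 2-fold. ADGRF5 rose by 5.53 (SE 0.31, adjusted p = 0.00193, 2 against 4 arrays), and MGP (5.33), KISS1 (4.97), SLC14A1 (4.92) and COL4A5 (4.25) rose too. GPAT2 fell by 6.22 (SE 0.28, adjusted p = 0.00193), MME by 4.88, TOP2A by 2.75 and CDKN1C by 2.69, while FGF2 at -0.24 did not pass (adjusted p = 0.606). The calls of OXTR (4.95), C3 (-6.59), EPB41L3 (-4.97), FBN2 (-4.02), LMNB1 (-2.79) and MKI67 (-2.06) were lost without either LGLL array: without replicate 1 the changes were 4.55, -6.56, -5.35, -3.93, -2.71 and -2.09, and without replicate 2 they were 5.36, -6.63, -4.60, -4.11, -2.87 and -2.03. Without later-passage replicate 2 EPB41L3 (-4.75) was not called either, and with the mean of all probe sets MGP moved to 2.75, FBN2 to -2.36 and COL4A5 to 1.89. All 25 mitosis genes fell, 25 also over the list alone, with a median of -2.47 (adjusted p = 0.482 with an estimated correlation). Of 24 collagens 13 rose, 1 fell and 10 did not pass (15 and 1 over the list alone), with a median of 1.65 (adjusted p = 0.482 with an estimated correlation), and 1.04 with no filter. The collagen median was 2.61 against later passage and 0.40, with 1 gene called, against early passage. The value against both groups thus came mainly from the later-passage arrays. The count of calls was 390 without LGLL replicate 1 and 441 without LGLL replicate 2, and 1566 and 1614 without later-passage replicate 1 and 2. Because the normal groups lie far apart, for 873 called genes the LGLL arrays did not both lie beyond all normal arrays on the same side. In 28% of genes both LGLL arrays did so, against 13.3% by chance.

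In both separate LGLL comparisons 13 genes changed in the same direction. ADGRF5, CAVIN4, COL4A5, HHIP, PCOLCE2, PRSS3, SYT16, TNFRSF21 and ZIC1 rose, and CDKN1C, GPAT2, IGLC1 and TENM2 fell. Not all of these are particular to LGLL. CAVIN4, COL4A5, SYT16 and TNFRSF21 were also called higher, and IGLC1 and TENM2 lower, from early to later passage in normal cultures. Independent lists would share 2.2 higher and 2.12 lower genes, and 1 gene changed in opposite directions. Simulated unchanged groups with shared LGLL arrays gave a mean of 0.02. No gene was changed in any of these simulations, so few were called and overlaps near 0 were fixed in advance. They do not show sharing beyond what real changes in the groups would give. The changes correlated at 0.301, below the 0.5 in simulation, with a covariance of 0.297 against 0.065. The simulated values already include the spread of the shared arrays, but no changed genes. Part of the overlap beyond independent lists may come from the shared arrays. The 13 became 204 without early-passage replicate 1, 5 without early-passage replicate 2 and 0 without any 1 of the other arrays, where limma left 959 to 1492 genes at unadjusted p under 0.05 in the comparison with early passage. Of the 5201 genes called against later passage, 3894 (74.9%) were also called between the normal groups with later passage on the same side and 11 on opposite sides, where independent lists would share 464.63 higher and 486.52 lower genes and simulation gave a mean of 0.03. Their covariance was 1.98 against 0.065 in simulation and the correlation 0.903 against 0.497. Both comparisons hold the later-passage arrays, and only 21 genes were called between LGLL and early passage. A large overlap therefore follows from the later-passage arrays standing apart. Of the 21 genes called against early passage, 14 (66.7%) moved the same way from early to later passage, 6 higher and 8 lower, and 3 moved in opposite directions, where independent lists would share 2 and 1.84 and simulation gave 0. Here the covariance was 0.131 against 0.066 in simulation and the correlation 0.138 against 0.502, and the shared early-passage arrays may add to the overlap.

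Over all comparisons 50 of 140 pairs of list and comparison passed camera with the preset correlation: 13 for LGLL against later passage, 8 for LGLL against early passage, 16 for later against early passage and 13 for LGLL against both. With an estimated correlation 0 passed, the lowest adjusted p being 0.482, and fry passed 46. The former has little power with 3 residual degrees of freedom. Even the mitosis list, with all 25 members called in LGLL against later passage, had an unadjusted p of 0.18 in it. Of the lists that passed camera, fry passed 12 of 13 for LGLL against later passage, 0 of 8 for LGLL against early passage (adjusted p = 0.0908 to 0.445), 12 of 16 for later against early passage and 11 of 13 for LGLL against both. The lists not passed by fry include mitosis (adjusted p = 0.121), DNA replication (adjusted p = 0.0517), interferon response and macrophage markers between the normal groups. With single arrays left out, 49 to 83 passed, the largest number without early-passage replicate 1. In the simulations 24 unchanged pairs passed camera over 20 sets, so some of the 50 passed pairs may be false.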

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

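The alternatives were planned except for the list medians, of which only quantile normalization was planned; every other alternative for a list median was chosen after the data were seen. The counts against later passage and between the normal groups stayed within 1.5 times their values under every alternative except with single arrays left out, where the lone array left in a group is assumed to vary like the other groups. With 1 array left out the counts ranged from 2934 to 5274 for LGLL against later passage, 0 to 350 against early passage, 2852 to 3825 for later against early passage, 390 to 2552 against both, 0 to 204 for genes called in both LGLL comparisons and 49 to 83 for lists. The filter at the 75th percentile left 10 calls against early passage and 5 in both, with fewer genes tested. Fitting only the arrays compared left 0 and 0 (limma, 1468 genes at unadjusted p under 0.05 against early passage), with fewer arrays to estimate the spread. An adjusted p under 0.10 gave 67 against early passage, 3742 against both and 49 in both comparisons, and a minimum of 2-fold gave 1564 against both. With the replicate number as a block 5 were called against early passage and 2 in both comparisons, and the cause was not tested. The replicate differences of the groups correlated at 0.034, -0.064 and 0.018, so no pairing by number showed. This cannot exclude a pairing, since the early-passage difference also holds the macrophage and interferon transcripts of replicate 2. With an estimated correlation 0 lists passed. With fry 46 passed, but none of the 8 lists that camera passed for LGLL against early passage were among them (adjusted p = 0.0908 to 0.445), nor were the mitosis and replication lists between the normal groups (0.121 and 0.0517). Without early-passage replicate 2 the list medians of LGLL against early passage turned negative for matrix glycoproteins (-0.24, with a range of -0.24 to 0.094 over left-out arrays) and for hypoxia and glycolysis (-0.21, with a range of -0.21 to 0.40), 2 lists that passed the set test in that direction only there; the cause was not tested. Of the gene values in the text 3 turned their direction, none of them called: IL6 against early passage without early-passage replicate 1 (-0.47) or LGLL replicate 1 (-0.19), CXCL12 against early passage without LGLL replicate 2 (-0.09) or with the mean of all probe sets (-0.003), and LMNB1 between the normal groups without early-passage replicate 1 (-0.07). Under quantile normalization 186 of 187 kept their side of the threshold and 1 was not tested. The mean of all probe sets ended the calls of COL4A5 (2.16), PSG9 (2.63), ITGA2 (2.56) and GAS1 (-2.36) against early passage, of HOXD9 against later passage (-0.23), and of HOXD9 (0.26) and CDKN2A (1.20) between the normal groups. The signal of a single probe set over its background was not analysed here, so small changes of genes with low signal are the least certain.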

Other observations

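The tests of explanations below were chosen after the results were seen, except that quantile normalization had been chosen beforehand. Beyond the gene groups described above, matrix glycoproteins and proteoglycans followed the collagens. Of 23 tested, 19 rose, 2 fell and 2 did not pass in LGLL against later passage (20 and 2 adjusted over the list alone, median 2.87, adjusted p = 0.482 with an estimated correlation). Between later and early passage 1 rose, 18 fell and 4 did not pass (2 and 20 over the list alone, median -3.40, adjusted p = 0.482 with an estimated correlation). Of 10 pericyte markers 8 rose, 1 fell and 1 did not pass in LGLL against later passage (8 and 1 over the list alone, adjusted p = 0.482 with an estimated correlation), and of 10 osteoblast genes 7 rose and 3 did not pass (7 over the list alone, adjusted p = 0.482 with an estimated correlation). Of 17 WNT genes 10 rose, 2 fell and 5 did not pass in LGLL against later passage (10 and 2 over the list alone, adjusted p = 0.482 with an estimated correlation). Of 19 BMP pathway genes 9 rose, 3 fell and 7 did not pass (10 and 3 over the list alone, median 2.19, adjusted p = 0.718 with an estimated correlation), a list that no longer passed without later-passage replicate 1 (1.94), later-passage replicate 2 (2.45) or LGLL replicate 2 (1.48), or with the mean of all probe sets (1.33), and had a median of 1.21 with no filter. Between later and early passage 8 of 15 macrophage markers fell and 7 did not pass (11 lower over the list alone, median -4.09, adjusted p = 0.726 with an estimated correlation), with medians of -2.01 without early-passage replicate 2 and -6.17 without replicate 1. Of 26 interferon response genes 5 fell and 21 did not pass (5 over the list alone, median -1.84, adjusted p = 0.83 with an estimated correlation), which no longer passed without early-passage replicate 2 (-0.43), without later-passage replicate 1 (-1.40) or with the filter at the 75th percentile (-0.68), and had a median of -2.96 without early-passage replicate 1.

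The later-passage normal arrays stood apart from the other 4. Array scaling is argued against, since 5037 genes were still called in LGLL against later passage after quantile normalization. Passage number acting alike in every culture is argued against as well: over the 4614 genes called between the normal groups, the LGLL cultures of the same passage range moved by a median of -0.01 in the direction of later passage (quartiles -0.27 and 0.28), where later passage itself moved by 1.38 (quartiles 0.96 and 2.2). A lower share of MSCs beside cells without MSC transcripts would lower MSC markers alike, but their changes had an interquartile range of 3.37, with LUM at -7.95 and VIM at 0.20. This bears only on cells that lack every marker of the list. Cells that share some of them, such as VIM, would blunt those falls, so a lower share of MSCs beside such cells stays open. More population doublings in the later-passage normal cultures, another or altered stromal population and a mislabelled sample stay open and were not tested, so the comparison with later passage may hold little that belongs to LGLL.

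The interferon and macrophage lists passed the set test as lower in LGLL than in early passage, but 0 of their members were called, and neither passed with an estimated correlation (adjusted p = 0.641 and 0.61). Early-passage replicate 2 alone may account for most of the interferon difference, since without it the list median went from -1.80 to -0.33, although the list still passed (adjusted p = 0.015). Whether it is the whole cause for the macrophage markers cannot be told apart from a difference between groups: their median went from -2.89 to -0.73 without it, but LGLL replicate 1 was level with early-passage replicate 1 (-0.08) and only LGLL replicate 2 was lower (-1.58). Macrophages carried over from the marrow are a candidate explanation for that array: all 15 markers were higher there than in replicate 1, by a median of 3.14, while fibroblast and MSC markers differed by 0.15. T and NK cell markers (8 of 8, median 2.19) and erythroid and granulocyte markers (5 of 6, median 1.65) were higher there as well. Any carry-over need not be of macrophages alone, nor be limited to that array. The mean of the macrophage markers was 8.09 on early-passage replicate 1 and 8.01 on LGLL replicate 1, against 5.97 on LGLL replicate 2. An interferon response of the MSCs themselves cannot be told apart from one of these other cells, because the interferon genes' gap of 2.9 came with the macrophage markers, and a lower interferon response in LGLL stays open.

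The mitosis list passed the set test as lower in LGLL than in early passage, with 0 of 25 members called over all genes (adjusted p = 0.482 with an estimated correlation). Early-passage replicate 2 alone is argued against, with a mitosis median of -1.34 without it. LGLL replicates 1 and 2 each lay below early-passage replicate 1 (medians -1.58 and -1.1). Early-passage replicate 2 still added to the difference, since all 25 mitosis genes were higher there than in replicate 1, by a median of 0.86. A group difference is not established, as the list did not pass fry (adjusted p = 0.0908). Array scaling is argued against too, with a median of -1.71 after quantile normalization. Passage number alone cannot be told apart from disease: the mitosis median was 1.54 in the later-passage normal cultures, but these correlated with the LGLL arrays at no more than 0.755 and so are no close reference for passage. The labels describe the LGLL cultures as later, with senescence, and an effect of senescence or of the disease on proliferation stays open, as no sample separates them.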
